A study of Mus musculus with 2 samples.

How the data were processed

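PolyA RNA of adult mouse testis was measured in 2 libraries, 1 per biological replicate, which the labels put in 1 group. For each library a table per gene and a table per transcript were analysed. Expected counts, the estimated number of reads per gene or transcript, were made by the authors on assembly mm10 with GENCODE annotation M4, per the text file deposited beside the tables, from alignments to the transcriptome. The aligner and the quantifier are not given in the sources used here, nor is the kit's use of strand. TPM, a length-corrected relative abundance, was deposited by the authors over all rows, so the phiX row and every other control row belong to its total. FPKM values deposited by the authors are proportional to TPM within a library. The deposited percent column gives each transcript's share of its gene's TPM; shares were recomputed here from transcript TPM. Posterior mean counts and posterior mean TPM, also deposited by the authors, spread a prior over genes without reads and served as alternatives. Effective length was length less 35 bases, as 36-base reads would give.

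Rows were sorted by their identifier. There were 43346 mouse gene rows, the phiX174 row, 96 ERCC rows, and 26248 rows with a number in place of a gene identifier, which held 12 and 8 counts. Only mouse gene rows entered the library sizes and comparisons. Symbols, biotypes and positions came from GENCODE M21 on GRCm38, the same assembly as mm10 in another annotation release, matched on identifiers without version. Of the rows, 42462 matched and 884 did not, the latter with 225 and 349 counts. The depth was 4860 and 6624 expected counts on mouse genes, with 131 and 195 genes at non-whole values.

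Gene lists, pairs, tests, the rule for named genes and most alternatives were chosen before the data were examined. The rule named the 20 nuclear genes with the highest mean TPM, the 3 highest members and the lowest of each list, the 4 largest and 2 smallest ratios of each pair list, the 10 highest and 10 lowest ratios between the libraries among coding genes at a mean TPM of at least 5, and every gene of the isoform list. The lowest members of most lists were tied at 0, so their number is given. Genes named outside the rule are said to be so. Across the lists, 4 symbols had no row.

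Shares of counts were given 95% Wilson intervals, and a count of 0 was taken to allow up to 3 counts. Between the libraries, expected counts were rounded to whole numbers and scaled by edgeR 4.0.16 TMM factors of 1.11 and 0.903 (R 4.3.3). The ratio of replicate 2 to replicate 1 had an exact Clopper-Pearson interval, and a gene was counted when the ratio was at least 2-fold, the interval left out 1 and mean TPM was at least 1. DESeq2 1.42.0 size factors were the alternative and came out as 1 and 1. With 1 library on each side there is no replicate, so no p-value was computed for differences between the libraries. Log2 ratios used a prior of 0.5 counts, pair ratios log2(TPM + 0.1). The number of list members with a count was set against 10000 random lists of coding genes matched on length, and list median ratios against 10000 matched on counts. Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

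The rule for differing genes was tested on simulated counts of replicate 2 against replicate 1 for 4634 genes. The simulated counts varied by counting error only. It called 0.406% of 4434 unchanged genes, 8% of 100 genes changed 4-fold and 54% of 100 changed 10-fold. Among 400 simulated genes with 20 expected counts in replicate 1, it called 3.5% of unchanged genes and 100% of those changed 4-fold. Of 100 simulated lists of 15 genes, 98 shifted 4-fold and 1 unshifted list passed the upper percentile bound. The measured libraries differed by more than counting error, as given below, so these rates do not give the share of false calls in them.

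Alternatives covered the TPM threshold, FPKM or posterior mean values, the scaling, the pseudocount, the filter on low values, the size rule and leaving out each library. Rescaling TPM to mouse genes, a minimum of 3 counts and the alternatives for list members and X-linked genes with a count were added after the data were seen. Signal tracks and alignments were not analysed here, so whether the tables hold all reads of each library was not checked.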

Results

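PolyA-selected RNA from the testis of adult male mice of strain B6NCrl, 8 weeks old, was sequenced in 2 libraries, which formed 1 group of 2 biological replicates. No second tissue, age or treatment was measured, so the comparisons are between gene groups within each library and between the 2 libraries. The labels describe each sample as the testis of an individual mouse but give both the same donor entry, so the spread between the libraries may include technical as well as animal differences. Mouse genes held 4860 expected counts in replicate 1 and 6624 in replicate 2. One sequence, the genome of the bacteriophage phiX174, which is a common sequencing control, held 85.0% of all counts in replicate 1 (95% Wilson interval 84.6 to 85.4%) and 77.3% in replicate 2 (76.8 to 77.8%). It took 53.9% and 42.8% of the TPM total, and the 96 rows of ERCC control RNAs held 0 counts in both libraries. At this depth 1 count on a gene was worth a median of 48.0 TPM in replicate 1 and 48.5 TPM in replicate 2. TPM thresholds of 1 or 5 therefore removed almost no gene with a count. Whether the tables cover all reads of the libraries is not settled by the sources used here, so zeros and shares describe these tables. All intervals cover counting error only.

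The genes with the highest mean TPM included Smcp, Prm1, Tnp1 and Odf2, whose proteins pack or build the sperm head and tail, and Crisp2. Smcp, which encodes a protein of the sperm mitochondrial capsule (chromosome 3, 92583867 to 92588997), had a mean TPM of 3461 ± 3102 (SD, n = 2) from 10 and 46 counts. Prm1, the protamine that replaces histones on sperm DNA (chromosome 16, 10796326 to 10805839), had 3359 ± 3096 from 23 and 5 counts. Tnp1, a transition protein that precedes the protamines, had 2916 ± 3019 from 3 and 20 counts. Odf2, of the outer dense fibres of the sperm tail, had 2131 ± 2220 from 8 and 37 counts. Crisp2, of the family named cysteine-rich secretory proteins, had 1800 ± 2018 from 5 and 16 counts. The protein-coding gene Gm3448 also ranked among the 20 most abundant, with 18 and 24 counts, and its exons overlap those of Ermard on the other strand by 97 bases. The other members of the top 20 were mostly short or repeated noncoding genes, in which few counts give a high TPM. Gm42418, labelled a lincRNA in the annotation used, held 52.2 and 210 counts. Rn7sk, a small nuclear RNA that regulates transcription elongation, held 4.90 and 11 counts. The remaining noncoding genes were the 5S rRNA genes n-R5s58, n-R5s64 and n-R5s1, the snoRNAs Gm24130, Snord99 and Snord32a, the pseudogene Gm13588, the antisense gene Gm15564 and Mir6236. Snord99 reached its rank from 2 counts. Another 3 places belonged to identifiers without a name in the annotation used, of which ENSMUSG00000045999.9 held 189 and 221 counts and ENSMUSG00000082697.1 held 1 and 95.6. The 10 most abundant nuclear genes of each library took 7.73% ± 1.23 of the TPM total (SD, n = 2). In this ranking and the top 20, identifiers without a match in the annotation were counted as nuclear, although their position is not known.

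Germ cell genes held more of the counts than somatic genes of the testis. The 106 genes on the 5 germ cell lists took 3.09% of the mouse gene counts in replicate 1 (95% Wilson interval 2.64 to 3.61%) and 3.97% in replicate 2 (3.53 to 4.47%), and 57 of them had a count. The 65 genes on the 5 somatic lists took 0.473% (0.316 to 0.709%) and 0.287% (0.184 to 0.448%), and 20 had a count. The intervals of the summed germ and somatic lists did not overlap in either library. Elongating spermatid genes alone supplied 93 of the 150 germ cell counts in replicate 1 and 191 of the 263 in replicate 2. By interval, the Sertoli list (0.226% and 0.151%) overlapped the meiotic prophase (0.267% and 0.393%) and round spermatid lists (0.267% and 0.332%) in both libraries. The piRNA list (0.617% and 0.362%) stood clear of it in replicate 1 only. Spermatogonial genes, with 1 and 0 counts, lay below Sertoli genes, with 11 and 10. The lists were built from genes known for these cell types, so the larger germ cell share is not independent evidence of the tissue's makeup.

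**Figure D1:**
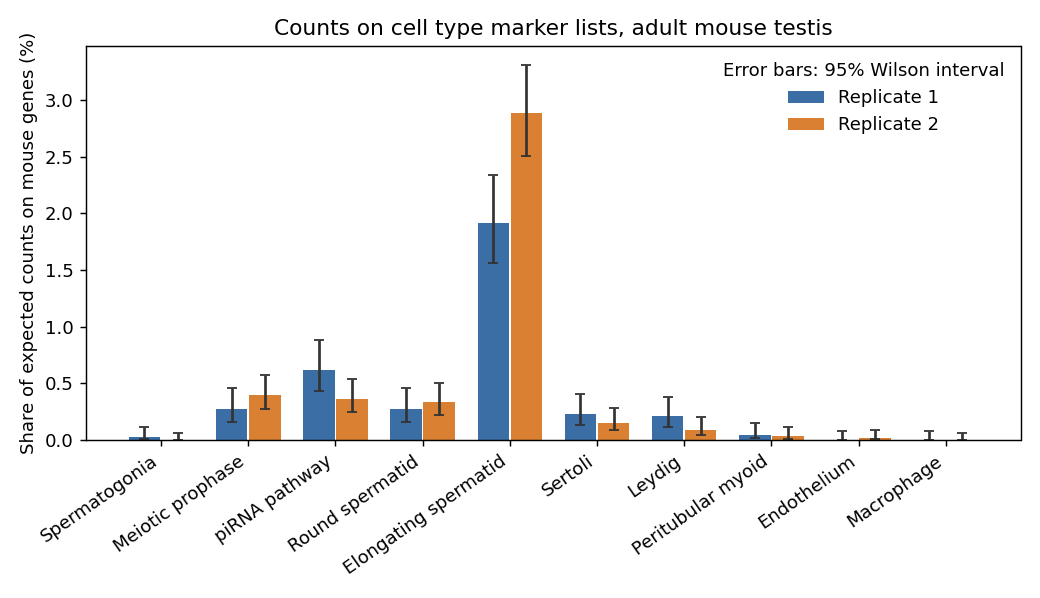
Share of expected counts on mouse genes (%, vertical axis) held by each of 10 marker lists, with 1 bar per library and error bars for the 95% Wilson interval of counting error. Elongating spermatid genes stand highest, at 1.91% in replicate 1 and 2.88% in replicate 2, and the macrophage list is at 0 in both.

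Elongating spermatid genes were the most abundant germ cell list. All of its 19 members except Spata3 had a count, against a median of 3 in 10000 random lists of coding genes matched on length, at the 100th percentile. They held 1.91% of counts in replicate 1 (1.56 to 2.34%) and 2.88% in replicate 2 (2.51 to 3.31%), with a summed TPM of 18234 ± 7257 (SD, n = 2). The 3 highest members were Smcp, Prm1 and Tnp1. Akap4, an X-linked scaffold protein of the sperm tail's fibrous sheath that was named outside the rule, had 11 counts in each library.

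Genes of meiotic prophase had counts for 14 of 27 members, against a random median of 5 (100th percentile), with a summed TPM of 822 ± 182. Stag3, a cohesin subunit of meiotic chromosomes, led with 3 and 4 counts, followed by Hspa2, a germ cell heat shock protein, with 5 and 2, and Sycp2, of the synaptonemal complex, with 2 and 1. Sycp3, Hormad1 and Rec8, other components of the meiotic chromosome axis that were picked after their values were seen, had 0, and the exons of Sycp3 overlap those of Chpt1 (0 and 47 counts) on the other strand. Of the 18 genes of the piRNA pathway, which silences transposons in germ cells, 11 had a count (random median 4), with a summed TPM of 1298 ± 509. Mael had 12 and 1 counts, Tdrd9 1 and 1, and Tdrd6 5 and 8. Round spermatid genes had counts for 13 of 24 members (random median 4), with a summed TPM of 1148 ± 421. Tbpl1, a TBP-related transcription factor, had 4 and 2 counts, Crem 0 and 1, and Actl7a 1 and 3. Spermatogonial genes stood apart from the other germ cell lists: Uchl1, with 1 count in replicate 1, was the only member with a count among 18 (random median 3, 7.16th percentile). For that list the summed TPM was 46.2 ± 65.4. Its share of mouse gene counts had a 95% Wilson upper limit of 0.116% in replicate 1, and in replicate 2 the 3 counts that a count of 0 allows correspond to 0.0453%.

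Among somatic cell types, Sertoli and Leydig cell genes were seen in part and at low counts, and the others nearly or wholly unseen. Sertoli cell genes had counts for 11 of 22 members (random median 5, 99.9th percentile), with a summed TPM of 989 ± 126. Cst9 had 3 and 1 counts, Clu, which encodes the secreted chaperone clusterin, 0 and 3, and Aard 3 and 1. Leydig cell genes had counts for 7 of 15 members (random median 3), with a summed TPM of 698 ± 113. Insl3, a Leydig cell hormone, had 2 and 1 counts, Ptgds 1 and 1, and Scarb1, a lipoprotein receptor, 1 and 2. Only 3 of the 22 Sertoli and 4 of the 15 Leydig genes reached 3 summed counts. Amh, Fshr and Inha of the Sertoli list had 0, as did Star, Cyp11a1 and Lhcgr of the Leydig list. These zeros were picked after their values were seen. Actg2, with 2 counts in each library, was the only 1 of 8 peritubular myoid genes with a count (summed TPM 294 ± 23.3), and Esam, with 1 count in replicate 2, the only 1 of 8 endothelial genes (27.7 ± 39.2). No member of the macrophage, blood, epididymis, immediate early and stress, or Y-linked lists had a count, of 12, 7, 9, 10 and 13 measured genes. Random lists matched on length had medians of 2, 1, 2, 2 and 2 members with a count, and the 5 lists were at the 4.34th, 13.8th, 5.90th, 5.67th and 2.81th percentiles. The myoid list was at the 29.1th and the endothelial list at the 27.8th. Of 7 X-linked multicopy spermatid genes, Cypt1 had 1 count in replicate 1 and Slxl1 1 in replicate 2 (summed TPM 157 ± 15), and their copies can share reads. Among 9 noncoding RNAs, Malat1 had 15 and 11.7 counts, Tug1 2 and 1, and Kcnq1ot1 0 and 3 (summed TPM 231 ± 49.4), whereas Xist had 0.

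Mitochondrial genes held 8.30% of mouse gene counts in replicate 1 (7.57 to 9.12%) and 5.47% in replicate 2 (4.94 to 6.04%), with a summed TPM of 34830 ± 5454. The rRNA genes mt-Rnr2, with 213 and 183 counts, and mt-Rnr1, with 52 and 137, supplied most of them, and mt-Co2 followed by TPM. Of 37 mitochondrial genes, 13 had a count. Nuclear copies of mitochondrial sequence can share these reads, and values such as 36.5 and 0.03 counts for mt-Co2 are estimates from shared reads.

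Protein-coding genes on the X chromosome had counts less often than those on any autosome. Of 941 X-linked coding genes, 98 had a count in either library, or 10.4% (95% Wilson interval 8.62 to 12.5%), against 19.6% of 20337 autosomal genes. The autosomes ranged from 13.9% on chromosome 7 (12.4 to 15.5%, overlapping the interval of X) to 25.4% on chromosome 5, and X was the lowest of 20 chromosomes. It was the lowest in each library as well, with 49 genes (5.21%) in replicate 1 and 58 (6.16%) in replicate 2. X-linked genes held 1.54% and 1.53% of coding counts. Among genes at a TPM of at least 1 in both libraries the medians went the other way, with an X to autosome ratio of 1.21 ± 0.173 (SD, n = 2) and X at rank 17 of 20 from the lowest, but only 9 X-linked genes entered and each needed a count in both libraries. None of 183 Y-linked coding genes had a count (95% Wilson upper limit 2.06%, which treats the genes as independent). Whether reads shared between Y-linked genes or with other genes play a part was not tested.

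**Figure D2:**
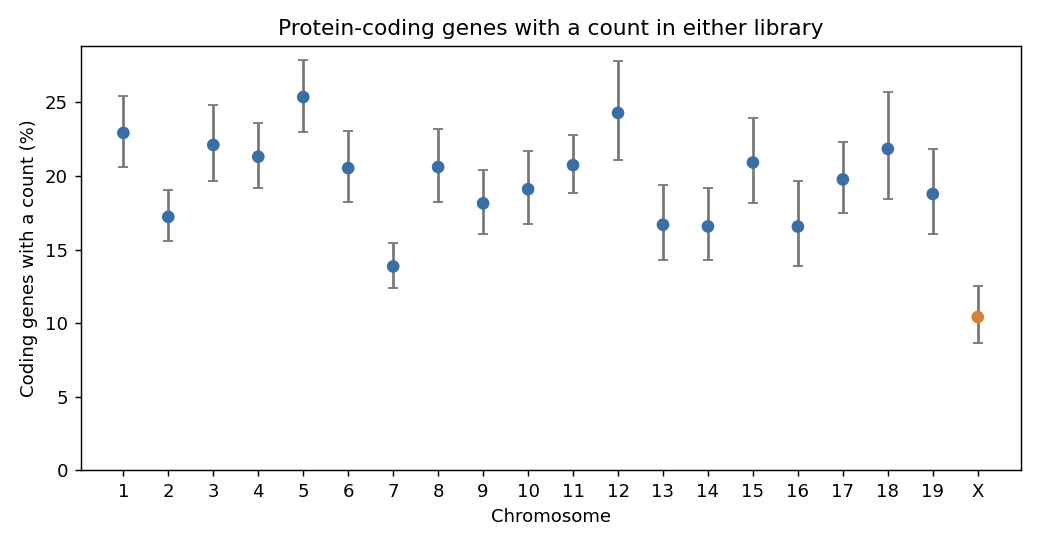
Share of protein-coding genes with at least 1 count in either library (%, vertical axis) for each autosome and the X chromosome (horizontal axis). Points are shares and bars 95% Wilson intervals, and X, at 10.4%, lies below chromosome 7, the lowest autosome, at 13.9%.

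Retrogenes active in the testis held more counts than the X-linked genes they were copied from. Over 12 pairs in the files, the autosomal copies had 12 and 11 counts and their X-linked parents 0 and 1. Cetn1, a centrin, had 2 and 5 counts against 0 for Cetn2, Pgk2, a glycolytic kinase, 4 and 4 against 0 for Pgk1, and Utp14b 1 and 2 against 0 for Utp14a. Those 3 pairs were higher for the testis copy in both libraries. Rpl10l, with 2 and 0 counts against 0 for Rpl10, was the next pair by size. In 2 more pairs the testis copy was higher in 1 library, as in Rpl10l, while 5 pairs had no count and Pdha1, with 1 count in replicate 2, exceeded Pdha2. The other of the 2 smallest ratios was shared by pairs without a count. The median log2 ratio over pairs, on log2(TPM + 0.1), was 2.27 as a mean of both libraries, but 0 in replicate 2 and 4.08 in replicate 1.

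In 19 pairs of a widely expressed gene and its testis paralogue, the testis copy was higher in both libraries in 5, the general copy in 2, and the libraries went opposite ways in 5, all by TPM. Of the 2 pairs higher for the general copy, Tbp had 2 and 2 counts against 4 and 2 for Tbpl1, so only the length correction put it higher, and this pair was picked after its values were seen. Cox6b2, a subunit of cytochrome oxidase, had 2 and 1 counts against 0 for Cox6b1, Gapdhs, the sperm glycolytic enzyme, 2 and 4 against 0 for Gapdh, and Tuba3a 2.40 and 2.71 against 0 for Tuba1a. Ldhc, a lactate dehydrogenase of germ cells, had 8 and 6 counts against 0 and 2 for Ldha. Ratios were lowest for Aldoa, with 1 count in each library against 0 for Aldoart1, and for Taf7, with 0 and 1 against 0 for Taf7l. Across the list the testis copies held 38.4 and 33.7 counts and the general copies 11 and 14.7. Both pair lists were chosen for known testis expression, and reads shared between such copies leave single pairs uncertain.

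Counts per gene differed between the 2 libraries. Of 294 genes with 6 or more summed counts, 77 (26.2%, 95% Wilson interval 21.5 to 31.5%) lay outside the 95% binomial range. Across all 43346 genes, which are not independent replicates, Pearson's r of log2(TPM + 1) was 0.339 and Spearman's rho 0.323. A count and a TPM of at least 1 were found for 1025 genes in both libraries, for 2573 in replicate 1 and for 3081 in replicate 2. By the rule of a 2-fold ratio with an exact 95% interval that leaves out 1, 88 genes differed, 49 higher and 39 lower in replicate 2. With total count scaling the split was 29 higher and 44 lower, with DESeq2 size factors 51 and 26, and with phiX scaling 73 and 19. This compares 2 libraries and has no replicate check.

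Elongating spermatid genes were on both sides. Smcp was 4.14-fold higher in replicate 2 (exact interval 2.06 to 9.20), Odf2 4.16-fold (1.91 to 10.4) and Tnp1 6.0-fold (1.78 to 31.5). Odf1, of the outer dense fibres, had 0 and 28 counts, a lower bound of 8.40-fold higher against a floor of 3 counts in replicate 1 and of 6.39-fold by the exact interval. By contrast, Prm1 was 5.11-fold lower in replicate 2 (1.90 to 17.2), and Tnp2, a transition protein, had 6 and 0 counts, with bounds of 2.22-fold and 1.31-fold lower. Akap4, Oaz3 (11 and 7 counts) and Ldhc (8 and 6) did not meet the rule for differing genes. Akap4 and Oaz3 were named outside the rule for named genes. The exons of Oaz3 overlap those of Tdrkh on the other strand by 2255 bases.

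**Figure D3:**
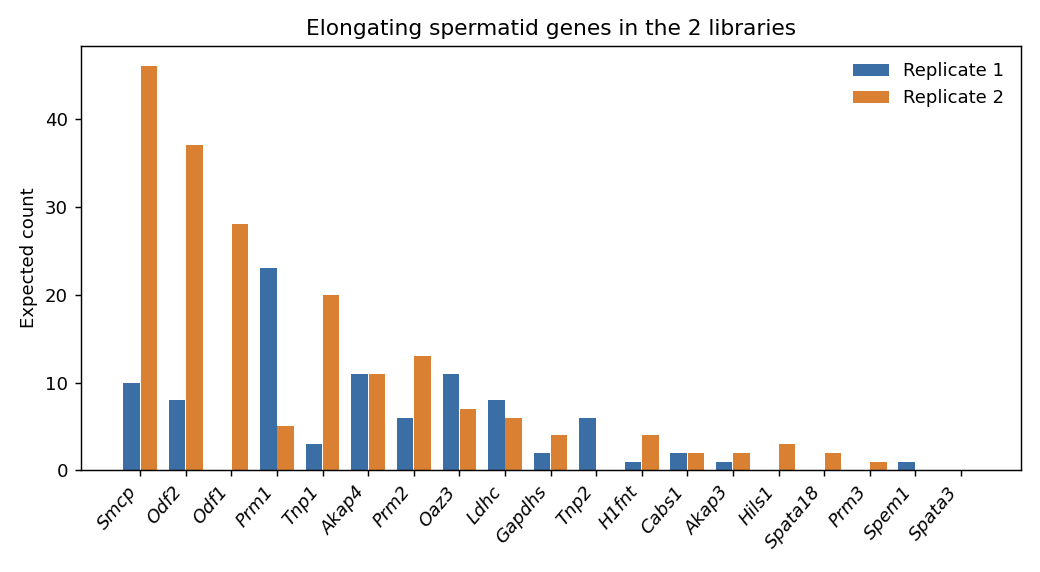
Expected counts (vertical axis) of the 19 elongating spermatid genes (horizontal axis), with 1 bar per library. Smcp has 10 and 46 counts and Prm1 23 and 5, in opposite directions.

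The largest ratio among coding genes belonged to Chpt1, a choline phosphotransferase, with 0 and 47 counts and lower bounds of 14.1-fold higher in replicate 2 against the floor and 11-fold by the exact interval. Its exons overlap those of Sycp3 on the other strand by 660 bases, and the sources used here do not say whether counting used strand, so reads of the pair cannot be told apart. Ssh2, a cofilin phosphatase, had 0 and 41 counts, with bounds of 12.3-fold and 9.56-fold higher. Cage1 and Spata4 had 0 and 10 counts each, Usp34 and Calm2 0 and 9, Zfp654 0 and 8, and Brdt, a testis bromodomain protein, and Coro2a 0 and 7. Usp34 overlaps Ahsa2 on the other strand by 2137 bases and Cage1 overlaps Riok1 by 75. Lower in replicate 2 were mt-Co2, Dusp23 with 22 and 0 counts (bounds of 8.15-fold and 6.08-fold), Gsg1, a germ cell gene, with 17 and 0 (bounds of 6.29-fold and 4.58-fold), Limd2 with 16 and 0, Pacs2 with 13 and 0, and Dkkl1 with 26 and 1. Dkkl1 was 28.9-fold lower in replicate 2, with an exact interval of 4.74 to 1184. Calb1 had 7 and 0 counts, Prr30 6 and 0, and Dnah7c 6.27 and 0, the last a non-whole estimate from shared reads. Gsg1 overlaps Fam234b on the other strand by 293 bases and Limd2 overlaps Gm10840 by 11.

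Mitochondrial genes were the only list whose median ratio between the libraries lay in the outer 5% of its matched random lists. Their median log2 ratio of replicate 2 to replicate 1 was -1.19 over 13 genes, at the 1.23th percentile of 10000 random lists matched on counts. Including the 24 members without a count, which all take the value -0.15, sets the median to that value by construction. Within the list, mt-Rnr1 was 2.37-fold higher (1.71 to 3.33). Sertoli genes had a median of -1.37 over 11 genes (8.28th percentile), and meiotic prophase genes 1.43 over 14 (92.5th). Round spermatid genes had 1.07 over 13 (74.8th) and elongating spermatid genes 0.80 over 18 (79.9th). The piRNA and Leydig lists both had -0.15 (28.2th and 36.9th). Only 5 of these 14 meiotic, 5 of 13 round spermatid and 3 of 11 Sertoli genes had 3 or more summed counts. The medians of those lists therefore take few distinct values. Of the mitochondrial genes with a count 10 of 13 had 3 or more, and of the elongating spermatid genes 15 of 18. For the piRNA list it was 7 of 11 and for the Leydig list 4 of 7.

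The most abundant transcript of a gene differed between the libraries in 468 of 738 genes with 2 or more transcripts and a mean TPM of at least 5, or 63.4% (95% Wilson interval 59.9 to 66.8%). In most of these genes few reads pick that transcript, and the share that sampling alone would give was not computed. With 5 or more counts in both libraries it differed in 13 of 22. On the list of 10 genes with known germ cell isoforms, Hk1 had 4 counts in each library, and a transcript of 517 bases took 96.4% of its TPM in replicate 1 and 0% in replicate 2. Tcp11 had 2 and 12 counts with 0% and 38.2% for its leading transcript, and Adcy10 2 and 2 counts with 0% and 74.0%. Brdt, with 0 and 7 counts, had 65.5% in replicate 2. Crem and Cdyl had 100% on 1 transcript in replicate 2, from 1 and 3 counts, and Ace and Ppp1cc 100% in replicate 1, from 2 and 3. Kit and Prkaca had no count. Over the genes of this list with a count in a library, the median share of the leading transcript of that library was 96.4% in replicate 1 and 87.0% in replicate 2 (mean 91.7% ± 6.63, SD, n = 2). Counts as low as the 1 to 3 of Crem, Cdyl, Ace and Ppp1cc leave little room for a second transcript, so this median does not measure how far 1 transcript dominates.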

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

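The following values lie outside the main measurement and exceed 3 counts, the limit that a count of 0 allows. The phiX174 row held 27575 counts in replicate 1 and 22561 in replicate 2. Rows with a number in place of a gene identifier held 12 counts in replicate 1 and 8 in replicate 2, over 26248 rows.

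Few counts lay on mouse genes, 4860 and 6624. The test of strand was chosen after the result was seen. If counting had used the opposite strand, coding genes overlapped by a coding gene on the other strand would hold an excess of counts, above 1.5 times their share of exon length. The 2100 genes overlapped by 100 bases or more held 12.6% of nuclear coding counts and 11.1% of exon length. That is a ratio of 1.14 (1.08 to 1.20 from counting error), which argues against counting wholly on the opposite strand as the cause. The limit of 1.5 was set without computing what such counting would give. As the ratio lay above 1, counting of some reads on the opposite strand is not excluded, and it was not tested. No biological explanation was tested, and the number of reads that reached no gene was not analysed here.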

How the results depend on the processing

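Of 207 alternatives for 43 results, 143 gave the value as reported within its spread or within 1.5 times a count, and 64 moved it. No value past its threshold changed sign, and total count scaling turned the balance of genes higher and lower in replicate 2 from 49 and 39 to 29 and 44. For means of 2 libraries, leaving 1 out stays within the SD by construction. The cause of a move was not tested unless stated. Posterior mean TPM spreads a prior over genes without reads. It gave 32991 genes detected in both libraries, a top 10 share of 0.480%, 1 retrogene pair higher in both, a leading transcript share of 32.8%, and summed TPM of 114 for meiotic, 84.6 for piRNA, 105 for round spermatid, 272 for elongating spermatid, 70.0 for Sertoli, 76.4 for Leydig, 23.3 for myoid, 16.4 for X multicopy, 93.6 for noncoding and 1108 for mitochondrial genes. TPM rescaled to mouse genes, which drops phiX from the total and was chosen after seeing the data, gave a top 10 share of 15.8% and, in the same order, 1671, 2788, 2302, 36449, 2075, 1468, 606, 328, 489 and 73275. Without the 20 most abundant genes in the total, elongating spermatid genes summed to 6984, as Smcp, Prm1, Tnp1 and Odf2 were among them, and myoid genes to 322. With mitochondrial genes and controls kept in, the top 10 share was 57.6%, and by expected counts 2.06%. The phiX share was 48.4% of TPM.

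A minimum of 3 counts, also chosen after seeing the data, left 126 genes in both libraries and 6 X-linked genes, and members with a count fell to 0 for spermatogonia, 5 meiotic, 7 piRNA, 5 round spermatid, 3 Sertoli, 4 Leydig and 0 endothelial. Leaving out 1 library gave 2573 to 3081 genes, 49 to 58 X-linked genes, 3 to 6 retrogene and 9 to 11 paralogue pairs, a paralogue median of 0 to 1.41, and members with a count of 0 to 1 for spermatogonia, 6 to 13 meiotic, 8 to 10 round spermatid, 6 to 7 Sertoli and 0 to 1 endothelial; with 1 library a pair or gene needs to pass only once. Pseudocounts of 1 and 0.01 gave a paralogue median of 2.90 and 6.21, from 4.55. Total count scaling left 29 genes higher in replicate 2, phiX scaling left 19 lower, and total count scaling moved the piRNA median to -0.45. The other scalings kept 68 to 75 of the 88 genes. On TPM + 0.1 the meiotic median was 7.69. With members without counts included, the meiotic, round spermatid, Sertoli and mitochondrial medians were all -0.15, the value that each gene without counts takes. Such genes made up 13 of 27, 11 of 24, 11 of 22 and 24 of 37 members in that order, so this alternative says nothing about shifts of the genes with counts. Pearson's r over genes detected in both was 0.582.

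The X to autosome ratio without a filter has no value, as the autosomal median is 0. Comparisons between the libraries were not run with 1 library left out, as they need both. No paired analysis was possible because there is 1 group. Depth limits all of this: 126 genes had 3 or more counts in both libraries, and whether the tables hold all reads is open.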

Other observations

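Among the tests in this part, those of counting error, of late spermatids and of gene length, and the choice of gene families, were made after the result was seen; the tests of reads per molecule, shared reads and ribosomal protein genes were written before their values were computed, that of shared reads after the low X-linked share was known.

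Gene families picked after their values were seen are given as values, since setting them against random lists is then no test. Spata genes, named for spermatogenesis, had counts for 22 of 28 members (random median 5) and Cfap genes, of cilia and flagella, for 18 of 30 (random median 6). Axonemal dynein heavy chains (Dnah) had 11 of 15 (random median 5), led by Dnah8 with 9 and 17 counts. Catsper genes, of the sperm calcium channel, had 7 of 10 (random median 2). The general chaperonin genes Cct and Tcp1 had 8 of 9 (random median 1) and ribosomal protein genes 28 of 83 (random median 15). Olfactory receptor genes had counts for 5 of 1050 (random median 85) and keratin genes for 2 of 109 (random median 18).

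Counts per gene differed between the libraries, with 26.2% of genes with 6 or more counts outside the 95% binomial range of counting error alone. Among elongating spermatid genes, 4 lay above that range and 2 below it. Of 838 genes with exactly 2 counts, 64.2% held both in 1 library (95% Wilson interval 60.9 to 67.4%), against 50.1% for independent reads. All 3 values set single samples against counting noise, which separate samples would exceed in any case, so they do not say what adds to that noise. A different share of late spermatids, several reads counted per molecule and real differences between the samples cannot be told apart here, and no biological explanation was tested, as there is 1 group.

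X-linked coding genes had counts less often than those of any autosome. Gene length does not account for it: 98 had a count, against a median of 186 in 10000 length-matched lists of autosomal genes (95% of lists from 162 to 209), at percentile 0. Reads shared with other genes could hide X-linked genes, as 34.1% of them had under 90% of their 32-base words to themselves, against 18.4% of autosomal genes. Among genes above that share, 12.9% of X-linked genes had a count (95% Wilson interval 10.5 to 15.8%), still below chromosome 7, the lowest autosome, at 16.2% (14.4 to 18.2%), though the intervals of X and chromosome 7 overlap. Silencing of the X in meiosis, known from textbooks, was not tested, as the design holds no group for it.

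A hypothesis that ribosomal protein genes hold few counts was not borne out relative to the mean of coding genes. They held 51 counts, 4.02 times what their length gives at that mean (exact Poisson interval 3.0 to 5.29). Most coding genes had no count in either library and lower that mean. The comparison therefore cannot decide whether these counts are few for widely expressed genes. Short transcripts as the cause of low counts of single members required about the mean count per base or more, which held. Any family with many counts would meet this, so it does not show that length is the cause. A count was found for 28 of 83, against a random median of 15. Members without a count shared more of their words with other genes than members with one, by 5.57 percentage points (28.6 against 23.1%). That difference had a one-sided p = 0.0768 in a permutation test over the 83 genes, which treats the genes as independent. Reads lost to copies therefore cannot be told apart from chance.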
